A study of Mus musculus with 3 samples.

How the data were processed

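Peyer's patch phagocytes were measured by droplet single-cell RNA sequencing (10x Genomics Chromium 3' chemistry, NextSeq) in 3 libraries: Control, CpG and R848, each from 12 female C57BL/6Rj mice pooled before sequencing. Per the submitters' processing notes, the authors aligned the reads to mm10 and counted barcodes and UMIs with Cell Ranger version 2.0.0. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalisation by the authors. The other deposited files hold the cell barcodes and the gene names (Ensembl ID and symbol) that name the matrix columns and lines, and no measurement. The 27998 genes listed are the same in all libraries. The annotation release that the authors used is not given in the sources used here. Coordinates were taken by Ensembl ID from GENCODE release M21, which is built on GRCm38, the assembly called mm10, and were found for 59 of 59 genes looked up.

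Cells with at least 500 detected genes and at most 10% of UMIs from mitochondrially encoded genes were kept, which left 5304 Control, 5023 CpG and 5107 R848 cells. Doublets were scored in each library from 2 simulated doublets per cell and 50 nearest neighbours, and the highest-scoring cells were removed at 0.8% per 1000 cells: 225, 202 and 209 cells. Each library was clustered on its own from log-normalised counts with 2000 variable genes, 30 principal components, 15 nearest neighbours and the Leiden method at resolution 1. Clusters were named as X-like from 17 fixed marker lists. A marker score was the mean log2 ratio of the markers in a cluster to the mean profile of the 3 libraries, and names were tried in order: a class outside the sort with the highest score of all, proliferating, mature dendritic cell, and then the sorted class with the highest score. A cluster stayed unnamed where its 10 leading genes held more markers of another class, where under 3 own markers reached 5 CPM, or where no own marker led and its median depth was under that of the library divided by 3, which no cluster met. Limits on the scores in this naming were set after the data were seen: at least 2 for cells outside the sorted classes, 1 for proliferating cells and 0 for mature dendritic cells, and a margin of 0.5 between macrophage-like and LysoDC-like cells. The cDC1 lineage joins cDC1-like clusters with mature clusters whose mean marker z-score per cell was highest for cDC1 among cDC1, cDC2 and LysoDC, and it replaced the cDC1-like class after the treated libraries were found to hold no resting cDC1-like cluster.

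UMIs were summed over the cells of a class in each library and scaled to CPM of that sum. The log2 ratio of 2 libraries was taken with 5 CPM added to both. With 1 library per group no test was run. Levels carry exact Poisson intervals, ratios of counts exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95%. A count of 0 is given with the limit set by 3 counts. The libraries held 43537067, 43767864 and 46556726 UMIs. Sums of the cDC1 lineage, cDC2-like, LysoDC-like and macrophage-like cells ran from 3945935 UMIs in the Control cDC1 lineage to 14661518 in R848 LysoDC-like cells. The mature dendritic cell-like class, compared in the closing part, held 2895816 UMIs in Control, 17524257 with CpG and 12914672 with R848.

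The 18 gene lists, the 17 marker lists, the named-gene rule and the alternatives were fixed before the data were examined, apart from the additions said here to be later. The rule took, per class, the 5 highest and 3 lowest log2 ratios for each treatment against Control, and the 3 highest and 3 lowest for R848 against CpG. Eligible genes had at least 50 CPM and at least 20 UMIs in the higher library, a ratio interval that left out 1 and at least a 2-fold difference. Immunoglobulin and T cell receptor segments, haemoglobin, ribosomal protein and mitochondrially encoded genes and unnamed gene models were not eligible. Members of the lists described and both receptors were added, and cluster genes named in the closing part were chosen after their values were seen. For each list, members with at least 20 CPM in 1 of the libraries compared were measured, and the median was ranked among 10000 random lists of the same size drawn from 20 expression bins. The interval of a list median came from 200 Poisson resamples. Lists overlap: the maturation list shares 9 genes with the markers of mature dendritic cells, and the cell cycle list 12 with the proliferation markers. Of the list genes 4, and of the marker genes 9, were not among the matrix genes and were not analysed here. Results treated as answering the comparisons, 34 list counts and 3 shares of mature cells, were chosen after the first values were seen.

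Free RNA was estimated per library from the complement genes C1qa, C1qb and C1qc in mature dendritic cell-like cells, which gave 4.79% of UMIs in Control, 2.59% in CpG and 2.51% in R848. Alternatives were a pseudocount of 1 or 20 CPM, no expression minimum or 100 CPM, median-of-ratios scaling, the mean of per-cell CPM, a filter of 1000 genes and 5% mitochondrial UMIs, no doublet removal, Leiden resolution 0.5 or 2.0, joint clustering, clustering without response-list genes, naming each cell from its own scores, removal of 5% free RNA, cells thinned to 3500 UMIs, LysoDC-like and macrophage-like cells merged, and mature cells moved to their lineage. After the data were seen, removal of the estimated free RNA, LysoDC-like cells without R848 cluster 7, R848 mature cluster 12 placed in the cDC1 lineage, and LysoDC-like cells without Control cluster 17 were added.

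The ratio intervals were tried on simulated data, in which both libraries were Poisson draws from 1 class profile apart from the set folds. Variation between cells, clusters or libraries was not simulated, nor was the cDC1 lineage. In simulated Poisson counts, with 50 genes per class set to each of the folds 0.25, 0.5, 2 and 4, ratio intervals covered the true value for 95.8%, 95.1% and 94.3% of genes in cDC2-like, LysoDC-like and macrophage-like cells, 0 genes without a set difference passed 2-fold, and the interval left out 1 for 50 of 50 genes at each set fold in each class. A separate simulation held 1200 cells of 4 classes and 60 added doublets, each of a cDC1-like and a macrophage-like cell. Of these doublets 57 were among the 60 highest scores. Doublets with mature cells or of other pairs of classes were not tried. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. B cell-like, plasma cell-like, T cell-like, proliferating and unnamed cells entered no comparison. Genes with 1 of the 56 symbols shared by several Ensembl IDs were kept apart by ID. Values of 2 genes are not reported here.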

Results

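Peyer's patches are the lymphoid follicles of the small intestine, where phagocytes sample material from the gut lumen. The libraries hold CD11c-positive phagocytes sorted from mouse Peyer's patches: conventional dendritic cells of types 1 and 2 (cDC1 and cDC2), LysoDC, which are monocyte-derived dendritic cells that make lysozyme, and macrophages. One library came from untreated mice (Control, not mock-injected). The CpG library came from mice given 125 µg of CpG, a DNA agonist of TLR9. The R848 library came from mice given 10 µg of R848, an agonist of TLR7. Both agonists were given by intraperitoneal injection 9 h before collection. Each library pooled 12 mice, with 88, 85 and 90 Peyer's patches for Control, CpG and R848. There was 1 library per group and so no replicate. Every interval given here is a 95% interval that covers counting error only, except 1 in the closing part that came from resampling genes.

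The Control library held 43537067 UMIs (unique transcript molecules) over 5344 cell barcodes, the CpG library 43767864 over 5049 and the R848 library 46556726 over 5133. The median cell had 7494, 7501 and 8223 UMIs and 2060, 2059 and 2177 detected genes in the same order. After filtering and doublet removal, 5079, 4821 and 4898 cells were kept. Expression is given as CPM, the UMIs of a gene scaled by the summed UMIs of its cell class.

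The first question was which phagocyte classes each library held. In the Control library, cDC2-like cells were the most numerous class named, with 35.4% of kept cells (exact binomial interval 34.0 to 36.7). LysoDC-like cells made up 24.0% (22.8 to 25.2), macrophage-like cells 13.1% (12.2 to 14.1) and cDC1-like cells 9.12% (8.34 to 9.94). Lysozyme did not separate LysoDC-like from macrophage-like cells: Lyz1 stood at 17622 CPM in the largest LysoDC-like cluster and 20589 CPM in macrophage-like cells, and the complement gene C1qa at 7961 and 10825 CPM. Cd4, a macrophage marker used in the naming, stood at 3.82 and 203 CPM. Mature dendritic cell-like cells, which carry the lymph-node homing receptor Ccr7 and the actin-bundling protein Fscn1, made up 58.7% (57.3 to 60.1) of the CpG library and 44.8% (43.4 to 46.2) of the R848 library, against 10.1% (9.30 to 11.0) of the Control library. With all response-list genes kept out of the clustering, these shares were 58.4%, 44.5% and 2.84%. No cluster of the treated libraries was named resting cDC1-like, which sets no limit on the share of such cells. cDC2-like cells made up 10.5% (9.62 to 11.4) with CpG and 10.3% (9.45 to 11.2) with R848, LysoDC-like cells 16.0% (15.01 to 17.1) and 24.1% (22.9 to 25.3), and macrophage-like cells 8.73% (7.95 to 9.57) and 14.9% (13.9 to 15.9). These shares leave out cells named mature. With mature clusters moved to their lineage by marker z-score, cDC2 cells made up 43.8% (42.4 to 45.2) of Control. They then made up 43.4% (41.9 to 44.8) with CpG and 36.7% (35.3 to 38.0) with R848. Some mature clusters moved to cDC2 had negative cDC2 z-scores, such as -0.131 in 744 CpG cells. The sort gates and the mixing of sorted populations can set these shares. When each cell was named from its own marker scores, without clusters, cDC1-like cells made up 1.78% of the CpG library and 1.69% of the R848 library, and with joint clustering 0.332% and 0.0817%.

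**Figure D1:**
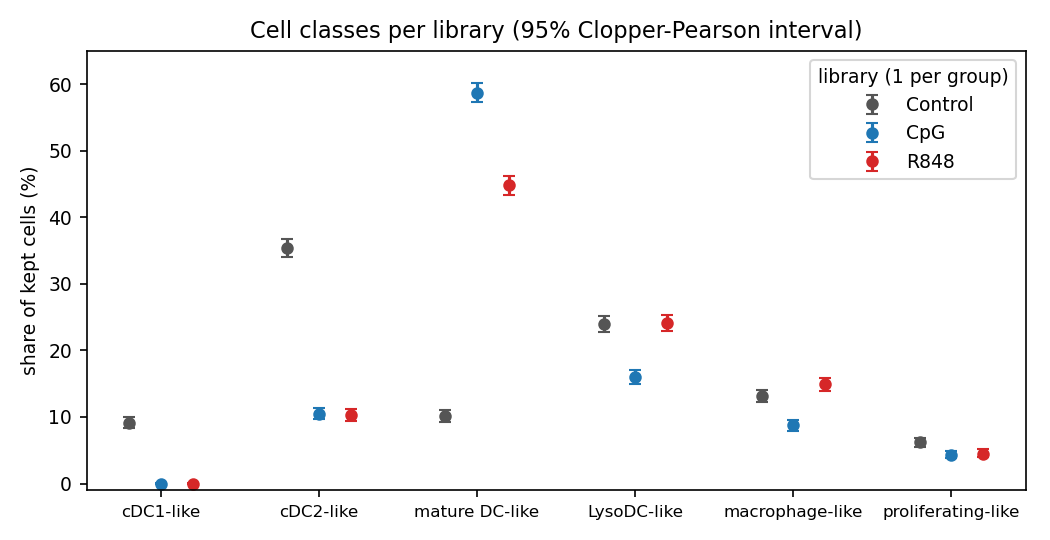
Share of kept cells (%, vertical axis) in each cell class (horizontal axis) for the Control, CpG and R848 libraries, 1 library each; points are shares and bars are 95% exact binomial intervals, which cover counting error only. Mature DC-like cells reached 58.7% with CpG and 44.8% with R848, against 10.1% in Control.

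Tlr7, the receptor of R848 (ENSMUSG00000044583, mm10 chromosome X, 167304929 to 167330558), was measured in LysoDC-like cells at 17.8 CPM in Control (exact Poisson interval 15.5 to 20.3) and in macrophage-like cells at 28.2 CPM (24.2 to 32.7). It was higher in both treated libraries: 48.1 CPM with CpG and 39.0 CPM with R848 in LysoDC-like cells, and 71.2 and 63.4 CPM in macrophage-like cells. In cDC2-like cells Tlr7 stood at 0.877, 1.11 and 0.757 CPM in Control, CpG and R848, near the 0.528, 0.613 and 0.704 CPM that free RNA was estimated to give. Resting cDC1-like cells of the Control library had 0 Tlr7 UMIs, which allows up to 0.893 CPM. Tlr9, the receptor of CpG (ENSMUSG00000045322, chromosome 9, 106222598 to 106226883), did not exceed 1.73 CPM in any class compared here. In LysoDC-like cells it stood at 1.57 CPM with R848 (23 UMIs, 0.994 to 2.35) and 0.325 CPM in Control (4 UMIs, 0.0885 to 0.831).

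The next comparison asked how LysoDC-like and macrophage-like cells of R848-treated mice differed from those of untreated mice. Ccl5, a chemokine that draws T cells, was the gene with the highest ratio in both. It stood at 4264 CPM with R848 against 10.7 CPM in Control LysoDC-like cells (398-fold, interval 335 to 476) and at 4850 against 6.97 CPM in macrophage-like cells, where free RNA was estimated to give 3.59 CPM in Control. Cxcl9, a ligand of the chemokine receptor Cxcr3 on T cells, was next among the chemokines, with 841 against 35.3 CPM (23.8-fold, 21.7 to 26.3) in LysoDC-like and 1203 against 15.4 CPM (78.3-fold, 64.1 to 96.6) in macrophage-like cells. Il12b, which encodes the p40 chain shared by the cytokines IL-12 and IL-23, stood at 383 against 23.6 CPM and at 140 against 4.76 CPM, and the LysoDC-like R848 level was 69.3 CPM without 1 cluster of 322 cells. Without the same cluster, the LysoDC-like R848 level of Ccl5 was 2806 CPM. In LysoDC-like cells the genes lowest with R848 included Il22ra2, the secreted decoy receptor of IL-22, at 913 against 3766 CPM (log2 ratio -2.04), and H2-DMb2, a chaperone of peptide loading on MHC class II, at 102 against 427 CPM (-2.01).

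The type I interferon-stimulated genes were higher together in these cells with R848: 32 of 32 measured members were at least 2-fold higher in LysoDC-like cells (median log2 ratio 1.80, counting interval 1.72 to 1.87) and 33 of 33 in macrophage-like cells (2.33, 2.28 to 2.40). Both medians stood at percentile 100 of 10000 random lists matched on expression. The Control LysoDC-like level of these genes depended on 1 cluster of 52 cells. Without it, Control Isg15 went from 96.8 to 59.2 CPM and Ifit1 from 20.5 to 7.19 CPM. Ifit3, an interferon-induced RNA-binding antiviral protein, stood at 246 against 5.23 CPM in macrophage-like cells, where Ly6a, a surface protein induced by interferon, stood at 199 against 3.17 CPM. Among chemokines, 8 of 10 measured members were higher in LysoDC-like cells and 7 of 10 in macrophage-like cells, and in both the neutrophil attractant Cxcl2 was lower (15.6 against 38.8 and 10.5 against 36.6 CPM). The medians were 2.71 and 3.08. Members of MHC class II presentation had medians of -0.79 and -0.87, with 2 of 12 and 3 of 11 at least 2-fold lower, among them H2-DMa at 387 against 1085 CPM and 121 against 380 CPM. Its macrophage-like median was -0.06 with all libraries clustered jointly and -0.24 after the estimated free RNA was taken away, while 7 members were lower with response-list genes kept out of the clustering.

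Dendritic cell maturation genes were also compared between R848 and Control. In LysoDC-like cells 10 of 21 measured members were at least 2-fold higher (median 0.98), led by Ccr7 at 241 against 6.58 CPM, a Control level no higher than the 6.84 CPM estimated for free RNA, and the maturation marker Cd83 at 57.1 against 10.1 CPM. In macrophage-like cells 4 of 20 were higher and 2 lower (median 0.27); the T cell costimulator Cd86 stood at 272 against 69.0 CPM and its inhibitory counterpart Cd274 at 201 against 53.4 CPM. Ccr7 in macrophage-like cells, at 38.7 CPM, was at the level of free RNA, 30.4 CPM. Clusters of proliferating cells were left out by markers that share 12 genes with the cell cycle list, so its values depend on the cycling cells left in a class. In macrophage-like cells 7 of 11 members were at least 2-fold higher (median 1.44), with the replication helicase subunits Mcm6 at 53.0 against 7.13 CPM and Mcm2 at 38.3 against 5.23 CPM. The LysoDC-like result rested on 1 cluster of 322 R848 cells with 899 CPM of Ccr7 and 1371 CPM of Il12b, whose macrophage score (-0.110) was above its LysoDC score (-0.153) and which was named LysoDC-like only by the margin set after the data were seen. Without it, 3 maturation members were higher and the log2 ratio of Ccr7 went from 4.41 to 1.66, with free RNA estimated to give 6.84 CPM in Control and 30.4 CPM with R848. The R848 LysoDC-like cells also included 698 cells with 24.1 CPM of Ccr7 and 134 cells with 2254 CPM of Cxcl10. The cluster of 134 cells had a neutrophil score of 1.43, above its LysoDC score of 1.14. A Control cluster of 53 LysoDC-like cells scored 1.84 for plasmacytoid dendritic cells and 0.468 for LysoDC. Both were named LysoDC-like only because the limit for classes outside the sort, set after the data were seen, was 2.

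**Figure D2:**
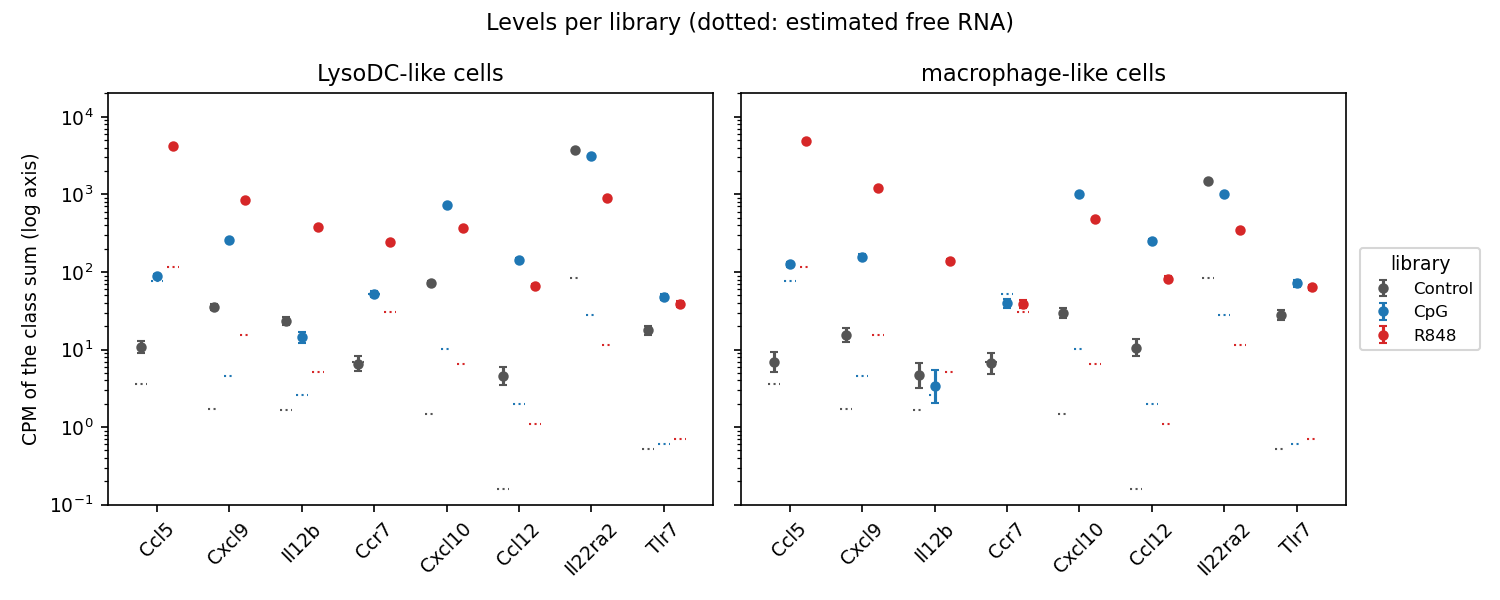
Expression of 8 genes (CPM, log axis) in LysoDC-like and macrophage-like cells of the Control, CpG and R848 libraries, 1 library each; points are class sums, bars are 95% exact Poisson intervals and short dotted lines give the level expected from free RNA. Ccl5 in LysoDC-like cells stood at 10.7, 88.5 and 4264 CPM in Control, CpG and R848.

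For cDC2-like cells, R848 against Control gave the highest ratios for interferon-stimulated genes and chemokines. Irf7, a transcription factor that drives type I interferon, stood at 326 against 6.84 CPM (47.7-fold, 38.0 to 60.8), Ccl5 at 818 against 35.9 CPM (22.8-fold, 20.5 to 25.3) and Cxcl10, like Cxcl9 a ligand of Cxcr3, at 97.9 against 4.21 CPM (23.3-fold, 17.2 to 32.1). Of 27 measured type I interferon-stimulated genes, 26 were at least 2-fold higher (median 1.72; 16 members with 20 CPM added, 10 with a 100 CPM minimum), as were 5 of 6 chemokines (median 2.17). The C-type lectin Cd209a, one of the markers used to name this class, was lower at 27.5 against 135 CPM (log2 ratio -2.11), and the receptor Notch2 at 45.7 against 131 CPM (-1.43). Lyz1, at 233 against 626 CPM, lay close to the level of free RNA in both libraries (172 and 459 CPM). MHC class II presentation had 0 of 13 members 2-fold different (median -0.02). Maturation genes had 7 of 26 members higher, and this count ran from 1 to 21 over the alternative settings, the highest with mature cells moved back to the cDC2 class.

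The cDC1 lineage was compared as a whole, because treated libraries had no resting cDC1-like cluster: mature cells made up 15.7% of its 549 Control cells and 100% of its 902 R848 cells and 1017 CpG cells. It made up 10.8% of kept cells in Control, 21.1% with CpG and 18.4% with R848. Mature clusters of 383 and 382 CpG cells and 329 and 228 R848 cells had negative cDC1 z-scores (-0.054, -0.057, -0.103 and -0.00268). They joined the lineage only because their cDC2 and LysoDC z-scores were lower still. The cDC1 marker Xcr1 stood at 1.95, 8.13, 23.8 and 33.1 CPM in them, against 51.0 CPM in the Control mature cluster. With R848 the highest ratios were those of Isg15, an interferon-induced ubiquitin-like protein, at 1882 against 42.6 CPM (44.2-fold, 38.0 to 51.8), Ramp3, a partner of calcitonin-family receptors, at 455 against 7.35 CPM (61.9-fold, 43.0 to 92.6), and the hormone gene Sct, at 155 against 0.760 CPM, where the Control value rested on 3 UMIs (204-fold, 69.7 to 993). Maturation genes were higher in 25 of 28 members (median 2.35), such as Fscn1 at 4480.4 against 335 CPM and the IL-15 receptor chain Il15ra at 331 against 16.5 CPM. MHC class II presentation was lower in 11 of 13 members (median -2.49), with H2-DMb1 at 28.9 against 920 CPM, and MHC class I processing was higher in 15 of 21 (median 1.45), with H2-Q6 at 399 against 57.3 CPM. Type I interferon-stimulated genes were higher in 23 of 27 (median 2.22). Naaa and Ppt1, lysosomal enzymes and markers used to name cDC1-like cells, were lower at 10.8 against 895 CPM and 38.8 against 1705 CPM, and Alox5ap, of the leukotriene pathway, at 3.61 against 276 CPM. These ratios set mature cells mostly against resting ones, and 9 maturation genes were also among the markers of the mature class.

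CpG against Control asked the same of the TLR9 agonist. In LysoDC-like cells the highest ratios belonged to Ccl12, a chemokine for monocytes, at 144 against 4.63 CPM (31.2-fold, 23.9 to 41.3), Sct at 87.5 against 1.22 CPM (71.9-fold, 43.3 to 129), Isg15 at 1088 against 96.8 CPM and Cxcl10 at 736 against 71.9 CPM. Without a Control cluster of 52 cells, the Control levels were 59.2 CPM for Isg15 and 15.9 CPM for Cxcl10. In macrophage-like cells they were Cxcl10 at 1024 against 29.5 CPM (34.7-fold, 30.02 to 40.4), Ifit3 at 234 against 5.23 CPM, its relative Ifit2 at 218 against 7.29 CPM and Ccl12 at 254 against 10.6 CPM (23.9-fold, 18.7 to 31.0). Type I interferon-stimulated genes were at least 2-fold higher in 32 of 33 members in LysoDC-like cells (median 2.04, 1.97 to 2.12) and 33 of 33 in macrophage-like cells (2.32, 2.23 to 2.42), both at percentile 100. Chemokines were higher in 6 of 10 and 7 of 10 members (medians 1.53 and 2.05). Ccl5 in LysoDC-like cells, at 88.5 CPM, was near the 77.6 CPM estimated for free RNA, and so was Ccr7, at 51.6 CPM with a ratio of 1.002 to its free RNA level. No MHC class II member was 2-fold lower in either class, although 5 were in macrophage-like cells when response-list genes were kept out of the clustering. The genes lowest with CpG included Tsku, a secreted proteoglycan, at 20.8 against 75.3 CPM and the translation initiation factor subunit Eif3f at 108 against 339 CPM in LysoDC-like cells, and Cpxm1, a carboxypeptidase-like protein, at 34.5 against 112 CPM in macrophage-like cells.

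In cDC2-like cells CpG gave its highest ratios to Irf7 (282 against 6.84 CPM; 41.2-fold, 32.8 to 52.5), Rtp4, an interferon-induced chaperone (186 against 9.73 CPM), Zbp1, a sensor of nucleic acids in the Z form (221 against 12.97 CPM), and Isg15 (600 against 43.6 CPM). Of 28 type I interferon-stimulated genes 27 were higher (median 2.20), and 3 of 6 chemokines were (median 1.47). That chemokine count was 1 with 5% free RNA taken away, 6 with cells named one by one and 8 with mature cells moved to their lineage. Among the lowest were the lectins Cd209a, at 1.34 against 135 CPM (log2 ratio -4.46), and Mgl2, at 13.1 against 72.0 CPM, both markers used in the naming, and the transcription factor Runx1 at 12.3 against 53.0 CPM. In Control, Cd209a was highest in 1 cluster of 201 of the 1796 cDC2-like cells (831 CPM). In R848 it was highest in 1 cluster of 88 of the 504 cDC2-like cells (168 CPM), no smaller a part of the class. The CpG clusters had 1.19 and 1.76 CPM. A different mix of cDC2-like cells with CpG cannot be told apart from a lower level within the same cells, and neither was tested. Cell cycle genes, measured after proliferating clusters were left out, were higher in 4 of 8 members (median 1.00015), with the helicase subunit Mcm5 at 49.9 against 14.1 CPM; the median was 0.33 when cells were named one by one. In the cDC1 lineage, Isg15 stood at 3053 against 42.6 CPM (71.7-fold, 61.6 to 84.0) and Il27, a subunit of the cytokine IL-27, at 262 against 1.52 CPM (172-fold, 79.0 to 470.5). Of its 10 measured cytokine genes 6 were at least 2-fold higher and 2 lower (median 2.62), with Il6 at 67.6 against 2.28 CPM and Ebi3, the partner chain of Il27, at 408 against 40.5 CPM. Maturation genes were higher in 25 of 29 members (median 2.95) and MHC class II presentation lower in 11 of 13 (median -3.05), with H2-DMb1 at 26.6 against 920 CPM. Gm2a, a lysosomal glycolipid-binding protein, was lower at 73.8 against 2559 CPM. The lineage ratios with CpG, like those with R848, set mature cells (100% with CpG) mostly against resting ones (15.7% mature in Control). Of the maturation genes, 9 were also markers of the mature class.

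R848 against CpG set both agonists side by side without the Control library. In LysoDC-like cells Ccl5 stood at 4264 with R848 against 88.5 CPM with CpG and in macrophage-like cells at 4850 against 126 CPM. Free RNA was estimated to give 77.6 CPM with CpG, so no fold is given. Il12b stood at 383 against 14.5 CPM (26.4-fold, 22.5 to 31.2) and at 140 against 3.43 CPM, the last near the 2.57 CPM of free RNA. Ccl8, another chemokine for monocytes, stood at 51.6 against 0.285 CPM in LysoDC-like cells (181-fold, 61.8 to 881) and at 122 against 0.571 CPM in macrophage-like cells (213-fold, 72.6 to 1033), each CpG value resting on 3 UMIs. Lower with R848 were Il22ra2 in LysoDC-like cells (913 against 3127 CPM), Ccl12 in macrophage-like cells (82.3 against 254 CPM; log2 ratio -1.57) and the leukotriene C4 synthase gene Ltc4s in both (78.6 against 301 and 131 against 512 CPM). Interferon-stimulated genes differed little, with medians of -0.28 and 0.03 and 1 of 33 and 0 of 33 members 2-fold different. Chemokines were higher in 5 and lower in 2 of 10 members in LysoDC-like cells (median 0.89; 2 to 3 higher at resolution 0.5, with cells named one by one or with mature cells moved), and higher in 5 and lower in 3 of 11 in macrophage-like cells (0.34). Maturation genes were higher in 8 of 21 members in LysoDC-like cells (median 0.73), and in 0 of them without the 322-cell cluster. The log2 ratio of Il12b in LysoDC-like cells was 4.31 with that cluster and 1.93 without it. Ccl5 in R848 LysoDC-like cells stood at 2806 CPM without it.

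In cDC2-like cells Ccl5 (818 against 159 CPM), Apol7c, an apolipoprotein L family member of mature dendritic cells (530 against 112 CPM), and the heat shock gene Hspa1a (255 against 63.0 CPM) were highest with R848 against CpG. Free RNA was estimated to give 115 CPM of Ccl5 and 35.6 CPM of Apol7c with R848. With CpG it was estimated to give 77.6 and 51.2 CPM. With mature cells moved back to the cDC2 class, the log2 ratios of Ccl5 and Apol7c went from 2.33 and 2.20 to -0.021 and -0.16. In the cDC1 lineage, whose cells were mature in both libraries but differed in make-up (Xcr1, a cDC1 marker, at 1.95, 8.13 and 91.4 CPM in its CpG clusters and 99.0, 23.8 and 33.1 CPM in its R848 clusters), 7 of 8 measured cytokine genes were at least 2-fold lower with R848 (median -1.33, -1.49 to -1.23), with Il27 at 53.3 against 262 CPM and Il6 at 8.76 against 67.6 CPM. With a mature R848 cluster of 106 cells, whose cDC1 and cDC2 scores lay close, placed in this lineage, 3 were lower. The median was then -0.70 and Il6 stood at 39.4 CPM. Mature CpG clusters of 744 and 66 cells, whose scores lay about as close, stayed with cDC2, so only the R848 side was varied. At a 100 CPM minimum 3 were also lower. In the cDC1 lineage the costimulatory receptor Cd40 stood at 315 against 1079 CPM. Tnip3, a cDC2 marker and inhibitor of NF-kB signalling, stood at 8.94 against 185 CPM (log2 ratio -3.77). MHC class II presentation had a median of 0.60, with 2 of 11 members higher, H2-Eb1 at 3448 against 1420 CPM and H2-Aa at 4263 against 1849 CPM. Asprv1, a retroviral-like aspartic protease, was the gene with the highest ratio, at 119 against 14.7 CPM (8.09-fold, 6.52 to 10.1), followed by the intermediate filament gene Vim at 315 against 94.1 CPM.

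**Figure D3:**
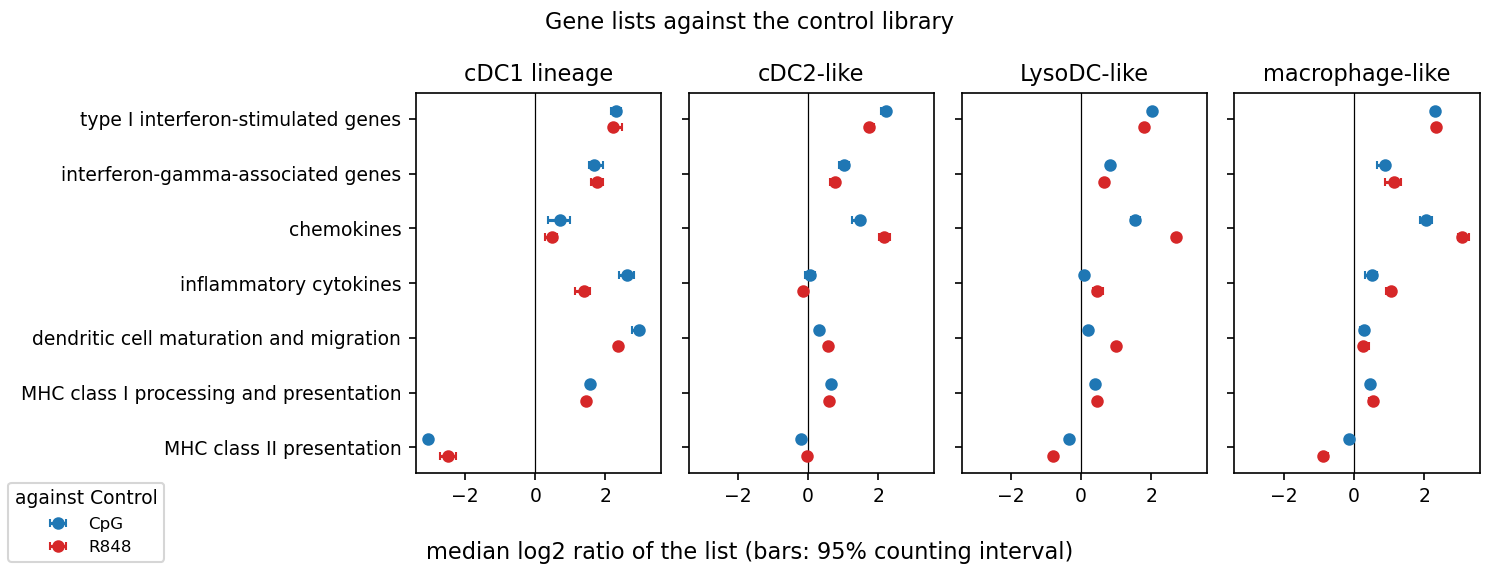
Median log2 ratio (horizontal axis, with 5 CPM added) of fixed gene lists in the 4 compared classes for R848 and CpG against Control, 1 library each; points are medians over measured members and bars are 95% intervals from Poisson resampling of the counts. Type I interferon-stimulated genes lay between 1.72 and 2.33 in the 4 classes, and MHC class II presentation reached -3.05 in the cDC1 lineage with CpG. In that lineage mature cells made up 15.7% in Control and 100% with CpG and with R848.

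The leading genes are protein-coding and lie in mm10 on chromosome 11 for Ccl5 (ENSMUSG00000035042, 83525778 to 83530518), Il12b (ENSMUSG00000004296, 44400063 to 44414033) and Ccr7 (ENSMUSG00000037944, 99144196 to 99155077). The chemokine genes Cxcl9 (ENSMUSG00000029417, 92321347 to 92328079) and Cxcl10 (ENSMUSG00000034855, 92346638 to 92348889) are neighbours on chromosome 5, and Ccl12 (ENSMUSG00000035352, 82101845 to 82103400) and Ccl8 (ENSMUSG00000009185, 82115185 to 82116799) are neighbours on chromosome 11. Isg15 (ENSMUSG00000035692) lies on chromosome 4 from 156199424 to 156200818, Irf7 (ENSMUSG00000025498) on chromosome 7 from 141262706 to 141266481 and Il22ra2 (ENSMUSG00000039760) on chromosome 10 from 19621998 to 19634681.

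The remaining fixed lists are summarised by their medians in cDC2-like, LysoDC-like and macrophage-like cells, in that order. Interferon-gamma-associated genes had medians of 0.77, 0.65 and 1.16 with R848 and 1.0096, 0.83 and 0.88 with CpG, and the GTPase gene Irgm1 was among their members at least 2-fold higher in all of these. MHC class I processing had medians of 0.60, 0.45 and 0.56 with R848 and 0.65, 0.39 and 0.45 with CpG. Inflammatory cytokines had medians of -0.13, 0.47 and 1.05 with R848 and 0.05, 0.08 and 0.51 with CpG, and Tgfb1, an inducer of IgA switching, stood at 90.0 against 255 CPM in LysoDC-like cells with R848. NF-kB and TLR primary response genes had medians of 0.09, 0.16 and -0.02 with R848 and 0.06, 0.07 and 0.06 with CpG. Maturation genes had medians of 0.32, 0.19 and 0.28 with CpG. These medians describe only cells not named mature, a name given by markers that share 9 genes with this list. With mature cells moved to their lineage, members at least 2-fold higher with CpG went from 2 to 20 in cDC2-like cells. In LysoDC-like cells they went from 4 to 9, although the 228 cells moved there had Lyz1 at 176 CPM. Nucleic acid sensors and their adaptors had medians of 0.32, 0.22 and 0.54 with R848 and 0.28, 0.35 and 0.51 with CpG. Phagocytosis genes had medians of -0.81, 0.06 and 0.01 with R848 and -1.04, 0.41 and 0.15 with CpG; 8 of them were also macrophage markers. With the estimated free RNA taken away the cDC2-like medians were -0.25 and -0.35, and C1qa there, at 193 CPM in Control, was below the 210 CPM estimated for free RNA. Lysosome and antimicrobial genes had medians of 0.13, 0.15 and 0.10 with R848 and 0.08, 0.18 and 0.13 with CpG. Genes of apoptosis and survival had medians of 0.39, 0.46 and 0.50 with R848 and 0.32, 0.30 and 0.37 with CpG. IgA induction and tolerance genes had medians of -0.12, 0.14 and 0.36 with R848 and -0.31, -0.05 and 0.04 with CpG, and glycolysis and hypoxia genes 0.03, -0.04 and 0.25 and then 0.42, 0.20 and 0.47. Dissociation stress genes, which respond to tissue digestion, had medians of -0.36, -0.24 and -0.12 with R848 and -0.12, -0.03 and 0.02 with CpG.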

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

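All tests in this part were chosen after the result was seen, except the median share of mature transcripts in the first pattern.

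Genes at least 2-fold higher in 1 class and at least 2-fold lower in another under the same treatment numbered 30 (counting a gene once per treatment). The 8 given here are those of named genes or members of the fixed lists, and none was tested. All 30 involve the cDC1 lineage, in which mature cells made up 15.7% in Control and 100% in the treated libraries. Il12b, a cytokine chain, had log2 ratios of 3.89 in macrophage-like cells (140 against 4.76 CPM) and -3.28 in the cDC1 lineage (10.1 against 142 CPM) with R848, a difference of 7.17. The Control lineage value came from 86 mature cells at 922 CPM, and with R848 cluster 12 placed in the lineage its R848 value was 219 CPM, above Control. Ccl17, a chemokine for T cells, differed by 4.84 between cDC2-like cells (332 against 120 CPM) and the cDC1 lineage (67.5 against 764 CPM) with R848. Cxcl9, with CpG, differed by 4.15 between macrophage-like cells (158 against 15.4 CPM) and the cDC1 lineage (76.0 against 175 CPM). Ldha, an enzyme of glycolysis, differed by 4.04 between macrophage-like cells (929 against 448 CPM) and the cDC1 lineage (61.9 against 527 CPM) with R848. Serpina3g, a protease inhibitor, differed by 3.97 between LysoDC-like cells (238 against 105 CPM) and the cDC1 lineage (15.9 against 143 CPM) with CpG. Il4i1, an amino acid oxidase, ran the other way with R848, differing by 3.34 between the cDC1 lineage (1524 against 298 CPM) and macrophage-like cells (200 against 407 CPM). Cd86, a costimulator, differed by 3.14 between macrophage-like cells (272 against 69.0 CPM) and the cDC1 lineage (86.1 against 209 CPM) with R848. Grn, the progranulin gene, differed by 2.71 between macrophage-like cells (676 against 216 CPM) and the cDC1 lineage (121 against 262 CPM) with R848.

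A cluster of 322 R848 cells (cluster 7), named LysoDC-like only by the margin set after the data were seen (macrophage score -0.110, LysoDC score -0.153), carried Ccr7 at 899 CPM, against 24.1 CPM in the main LysoDC-like cluster, beside Lyz1 at 11819 CPM. If doublets with mature cells were its whole source, 72 mature-cell genes would enter it at 1 common share. The median share was 8.85% (interval 5.31 to 12.1 from resampling these genes, which is not counting error). It was under the preset bound of 10% but not by more than its spread, so this test alone did not decide. Against each of the 7 mature clusters, at least 33.3% of abundant genes entered at a share under 5%, Lsp1 at 2.69% or less, while Ccr7 entered at 18.4% to 45.7%, and Ido1, at 249.8 CPM, was above every mature cluster (56.4 CPM or less), which argues against doublets as the whole source, though a part from doublets stays open. Free RNA is argued against by a median ratio of mature markers to their free RNA level of 31.1. A response of LysoDC-like cells to R848 stays open without support: the Ccr7 ratio of R848 to CpG, 4.67, restates the pattern, its CpG value is at the free RNA level, and with 1 library per group a response cannot be told apart from another difference of that library.

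In macrophage-like cells of both treated libraries, Ccr7, Cd86 and Cd274 were higher than in Control. For Ccr7 the higher of the ratios to the free RNA level was 1.27, consistent with free RNA from mature cells as its source. For Cd86 and Cd274 the lowest of the ratios was 32.5, which argues against free RNA for both of these genes. No biological explanation of the Cd86 and Cd274 values was tested, and treatment stays open as one.

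Eif3f, Notch2 and Slc39a1 were lower in all compared classes of both treated libraries, with a median log2 ratio of -1.41 that ran from -3.11 to -1.06. Free RNA, of which the Control library held more, is argued against as the cause, because the median after its removal was again -1.41. Between R848 and CpG the largest log2 ratio of these genes was 0.57 in size. A difference of the Control library unrelated to treatment could give this and cannot be told apart from an effect of both treatments, since 1 library stands for each group.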

How the results depend on the processing

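The alternatives that take away the estimated free RNA, leave out R848 cluster 7 or Control cluster 17 and place R848 cluster 12 in the cDC1 lineage were chosen only after the result was seen. Of 1371 alternative values of named genes, 761 stayed within their interval, 608 moved and 2 reversed. Of 3785 values of list medians, 2771 stayed, 1013 moved and 1 reversed. A reversal was a change of sign of a log2 ratio or list median at least 1 in size in the report. Smaller values that changed sign were not set apart from those that stayed or moved. Of 608 list counts, 546 stayed within 1.5 times and 62 did not. Of 91 shares, 61 stayed within their interval and 30 did not. Reversal was not defined for counts and shares. Median-of-ratios scaling moved all genes by 0.12 (log2) in the cDC1 lineage with CpG, by 0.17 and 0.16 in cDC2-like cells with R848 and CpG and by 0.10 in macrophage-like cells with R848. Thinning kept cells with at least 3500 UMIs, so it left out 95 of 549 Control, 195 of 1017 CpG and 184 of 902 R848 cells of the cDC1 lineage. Moving mature cells put 228 CpG cells with LysoDC by marker z-score, although their Lyz1 was 176 CPM. Sct in the cDC1 lineage and Ccl8 in LysoDC-like cells rest on 3 reference UMIs each. Except where a value itself shows it, the cause was not tested. Values below are counts of members at least 2-fold different unless said, each after its value in the report.

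With 1 CPM added, macrophage-like MHC class II members lower with CpG went from 0 to 1. With 20 CPM added, cDC2-like interferon-stimulated genes higher with R848 went from 26 to 16. Maturation genes higher went from 7 to 3 (cDC2-like, R848), 2 to 1 (cDC2-like, CpG), 10 to 6 (LysoDC-like, R848), 4 to 1 (LysoDC-like, CpG) and 5 to 3 (macrophage-like, CpG). Macrophage-like MHC class II members lower with R848 went from 3 to 1.

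With a 100 CPM minimum fewer genes were measured. Interferon-stimulated genes higher went from 23 to 10 (cDC1 lineage, R848), 25 to 12 (cDC1 lineage, CpG), 26 to 10 (cDC2-like, R848) and 27 to 13 (cDC2-like, CpG). Chemokines higher went from 5 to 3 (cDC2-like, R848), 6 to 3 (LysoDC-like, CpG) and 7 to 4 (macrophage-like, CpG). Maturation genes higher went from 7 to 4 and 2 to 1 (cDC2-like, R848 and CpG), 4 to 1 (LysoDC-like, CpG), and 4 to 2 and 5 to 2 (macrophage-like, R848 and CpG). Cytokines lower in the cDC1 lineage with R848 against CpG went from 7 to 3 (also 3 with cluster 12 in the lineage), and the cytokine median there with R848 against Control reversed from 1.38 to -1.55.

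Under other clusterings and namings, cDC2-like maturation genes higher with R848 (7) went to 1 at resolution 0.5, 1 at resolution 2.0, 2 with joint clustering, 1 without response-list genes, 2 with cells named one by one and 21 with mature cells moved. With CpG (2) they went to 7 without doublet removal, 0 at resolution 2.0, 1 with joint clustering, 0 without response-list genes, 4 with cells named one by one and 20 with mature cells moved. They went to 1 with median-of-ratios scaling, 0 with 5% free RNA taken away, 4 with thinned cells and 1 with the estimated free RNA taken away.

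Chemokines higher in the cDC1 lineage with R848 (1) went to 2 without doublet removal, 3 with cells named one by one, 2 with thinned cells and 2 with cluster 12 in the lineage, and with CpG (3) to 5 with cells named one by one. In cDC2-like cells with CpG (3) they went to 6 with cells named one by one, 1 with 5% free RNA taken away and 8 with mature cells moved. In LysoDC-like cells with R848 against CpG (5) they went to 2 at resolution 0.5, 3 with cells named one by one and 2 with mature cells moved.

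Macrophage-like MHC class II members lower with CpG (0) went to 1 with joint clustering and 5 without response-list genes, and with R848 (3) to 7 without response-list genes and 1 with the estimated free RNA taken away. LysoDC-like maturation genes higher with R848 (10) went to 3 with cells named one by one and 3 without cluster 7. With CpG (4) they went to 1 with 5% free RNA taken away and 9 with mature cells moved. Against CpG (8) they went to 0 with cells named one by one, 3 with LysoDC-like and macrophage-like cells merged, 2 with mature cells moved and 0 without cluster 7. Merging took macrophage-like maturation genes with R848 from 4 to 7. With mature cells moved, the log2 ratios of Ccl5 and Apol7c in cDC2-like cells, R848 against CpG, reversed from 2.33 and 2.20 to -0.021 and -0.16.

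Mature cells in Control (10.1%) went to 5.18% at resolution 2.0, 2.84% without response-list genes and 4.33% with cells named one by one. Naming cells one by one gave 48.8% with CpG and 39.3% with R848, and the stricter cell filter 43.0% with R848.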

Other observations

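The clusters and genes singled out in this part were chosen only after the result was seen. Mature dendritic cell-like cells were a different mix of clusters in each library. Il6 with CpG ran from 40.4 to 680 CPM between mature clusters. In the whole class, R848 against CpG, 5 of 10 measured cytokine genes were at least 2-fold lower (median log2 ratio -1.09), with Il6 at 33.0 against 246 CPM, Il27 at 28.5 against 117 CPM and Ebi3 at 108 against 362 CPM. Of 9 chemokines 4 were lower (median -0.69), among them Ccl3 at 8.75 against 82.8 CPM and Ccl4 at 12.2 against 87.4 CPM, both attractants of activated T cells. Aldh1a2, which makes retinoic acid, stood at 211 CPM with R848, 833 CPM with CpG and 113 CPM in Control. Of the 514 Control mature cells, 428 formed 1 cluster with a lower mature score (0.267) than cDC2 score (0.366) and Ccr7 at 1496 CPM, against 1939 CPM or more in each treated mature cluster. Against this Control class, MHC class II genes had medians of -1.14 with R848 and -1.90 with CpG, with H2-Ab1 at 4061 and 2447 against 12632 CPM. Glycolysis and hypoxia genes had medians of -1.36 and -1.25, with Ldha at 79.5 and 115 against 567 CPM. Il12b reached 2819.6 CPM in a mature cluster of 192 CpG cells and 2395 CPM in one of 106 R848 cells.

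In LysoDC-like and macrophage-like cells, R848 came with Ido1 and Ido2, enzymes of tryptophan breakdown: Ido1 stood at 102 against 13.3 CPM and 57.8 against 6.34 CPM (54.8 CPM in LysoDC-like cells without R848 cluster 7), and Ido2 at 67.5 (43.3 without cluster 7) against 6.33 CPM and 69.5 against 8.72 CPM. A Control cluster of 52 cells, named LysoDC-like only by the margin set after the data were seen (macrophage score 0.278, LysoDC score 0.195, Cd4 at 68.8 CPM), had Cxcl10 at 1413 CPM, Isg15 at 998 CPM and Ifit1 at 338 CPM, against 13.5, 63.9 and 7.49 CPM in the main LysoDC-like cluster. An unnamed cluster of 32 Control cells carried Nccrp1 at 1791 CPM. An unnamed cluster of 14 R848 cells carried Nccrp1 at 489 CPM and Aire, which drives expression of tissue antigens, at 199 CPM. An unnamed cluster of 28 CpG cells carried the monocyte marker Ly6c2 at 597 CPM and the acute-phase gene Saa3 at 875 CPM. B cell-like cells made up 1.48% of Control and 0.653% of R848 cells, plasma cell-like cells 0.871% of CpG and 0.531% of R848 cells, and T cell-like cells 0.270% of CpG cells. The Control B cell-like cluster and both plasma cell-like clusters shared the leading genes Cd79a, Jchain, Mzb1, Vpreb3 and Pou2af1. These names therefore do not separate B cells from plasma cells between libraries. Proliferating cells made up 6.18%, 4.34% and 4.49% of Control, CpG and R848 cells.

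Mitochondrially encoded genes had negative median log2 ratios to Control in both treated libraries. With R848 the medians were -0.80, -0.59, -0.94 and -1.02 in the cDC1 lineage, cDC2-like, LysoDC-like and macrophage-like cells. With CpG they were -0.61, -0.39, -0.49 and -0.59 in the same order. Only the macrophage-like median with R848 lay beyond 2-fold. In macrophage-like cells mt-Nd4 stood at 499.5 with R848 and 808 with CpG against 1592 CPM. Cytosolic ribosomal protein genes had medians of -0.76, -0.32, -0.31 and -0.14 with R848 and -0.79, -0.34, -0.34 and -0.23 with CpG in the same order.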
